A study of Mus musculus with 19 samples.

How the data were processed

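The values used were raw counts of reads per gene symbol in 2 tables, one for 2D culture and one for blastoids, which the authors deposited together with labels of each library. Per the submitters' processing notes, reads were aligned to the mouse genome mm10 with STAR 2.7.10b and counted per gene with HTSeq 0.13.5. The annotation release and the strand setting of the counting are not given in the sources used here, so counts of overlapping or antisense genes are uncertain. Examples are Pou5f1 with Gm19553, Krt8 with Gm36026 and Cdkn1a with AC167363.2. Polyadenylated RNA had been turned into libraries with Smart-seq2. Each table held 54352 symbols, of which 53700 matched exactly 1 gene of GENCODE M21 (37 of them through an older symbol), 112 matched several and 540 matched none. Gene coordinates (GRCm38), GC content, transcript length and the number of introns of the longest transcript came from that release.

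Libraries were grouped by the culture, treatment and day in their labels, giving 2 libraries in each 2D group and 3 on each blastoid day. Library totals ran from 2515381 to 4118725 counts in 2D and from 3684787 to 7607021 in blastoids. Replicates in both tables share only a replicate number, so they were not paired. The 2D libraries were fitted together, the blastoid libraries together, and for the comparison of day 1 with PlaB-treated 2D cells all libraries together. The biological coefficient of variation was 0.127 in the 2D fit, 0.258 in the blastoid fit and 0.25 in the joint fit.

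Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. Differential expression was tested with edgeR 4.0.16, using TMM scaling, robust dispersion estimates and the quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with 0.05 as the threshold. Adjusted p-values of single genes come from edgeR unless another tool is named. CPM values are TMM-scaled within the fit of the comparison. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and their p-values were adjusted over the lists of each comparison. The same test was run with the correlation estimated from the residuals. Few residuals were available for this, above all in the 2D fit of 4 libraries, where many lists had the same adjusted p of 0.68. A list that did not pass in this setting is therefore not shown to be unchanged. The simulations described below did not include this setting. Lists with fewer than 3 tested genes were not tested. Counts of list members are given after adjustment over all genes and, where they differ, after adjustment over the list alone. R 4.3.3 and Python 3.11.15 were used.

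The 21 lists were fixed before the data were examined: 2C genes, p53 targets, naive and general pluripotency, formative and primed pluripotency, trophectoderm, primitive endoderm, mesendoderm and gastrulation, feeder fibroblasts, splicing factors, integrated stress and unfolded protein response, immediate early genes, apoptosis regulators, S phase, G2 and M phase, ribosomal proteins, glycolysis and hypoxia response, cholesterol synthesis, epithelial junctions and fluid transport, Wnt targets, YAP targets and Nodal targets. More than one list holds 7 genes (Ascl2, Atf3, Cdx1, Cer1, Dkk1, Rps27l and Tdgf1). Of 24 feeder markers in the table, 3 still had a mean of at least 10 CPM on blastoid day 5, when feeder RNA was low.

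Genes were named by a fixed rule. It takes the genes with the largest log2 fold change in each direction that pass the threshold, have a mean of at least 10 CPM in the higher group and do not overlap between the libraries of both groups. Numbered gene models, pseudogenes and bare identifiers were left out. The rule takes 8 genes per direction for PlaB against control and for day 5 against day 1, 4 for day 1 against 2D PlaB, and 3 for each step between neighbouring days. It adds a fixed set of genes for each comparison and up to 4 members of each list with the smallest adjusted p. Where the lower group had 0 counts, the fold is a lower bound with a floor of 3 counts over the group. With 1 to 3 counts a ratio with its 95% counting interval is given.

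Scaling by total counts only, no filter other than a count above 0, a block for the replicate number and leaving out each library were run as alternatives for counts of genes, named genes and gene lists. DESeq2 1.42.0 and RLE size factors were run for counts of genes and named genes. For counts of genes alone, limma-voom, at least 10 counts in every library of either group, a log2 fold change of at least 1, thinning to the smallest total and only the libraries of the groups compared were run. Where leaving out a 2D library left 1 in its group, that library was assumed to vary like those of the other groups in the fit. Gene lists were also tested with camera with an estimated correlation, without multi-copy families and with fry. Fry asks whether the genes of a list move one way on balance and, unlike camera, does not compare them with other genes. The intron classes were also tested with scaling by total counts only, with introns from the union of exons and with only protein-coding genes without histone, olfactory receptor and Gm-numbered genes. After the data were seen, a correction of the GC trend was added, which removes from each library a loess curve (span 0.3) of log2 level on GC content. So were the same correction with transcript length, and leaving out libraries, the block and the estimated correlation for the intron classes. GC-rich genes in the text have at least 55% GC (2855 genes) and GC-poor genes less than 45% (5094 genes).

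The procedure was tested on simulated data with 200 changed genes among those tested. Far more were called in the real data, 5784 for PlaB against control and 7718 for day 5 against day 1. The Benjamini-Hochberg adjustment is stricter where fewer genes change, so the recovery given here is not that of the real data. For PlaB against control the procedure recovered 53% of genes changed 2-fold and 78% of those changed 4-fold, with 11 false calls among 10983 unchanged genes. For day 5 against day 1 it recovered 20% and 70%, with 7 false calls, and for day 1 against 2D PlaB 18% and 65%, with 2. Recovery was 24% and 80% from day 1 to 2, 33% and 86% from day 2 to 3, 23% and 83% from day 3 to 4, and 26% and 74% from day 4 to 5. For a difference between any days it was 18% and 75%. An added GC trend gave 3504 false calls for PlaB against control and 1535 for day 5 against day 1, and 7 in each after correction. Camera called the changed list in each of 3 simulated comparisons and 0 of 100 unchanged lists. Genes were simulated independently of each other, so these outcomes do not show how camera performs where the genes of a list are correlated. Splicing itself (intron retention or exon skipping) was not analysed here, since only gene counts were used.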

Results

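Polyadenylated RNA was measured in TT2 cells, a mouse embryonic stem cell line kept on a layer of growth-arrested mouse embryonic fibroblasts (feeder cells), and in blastoids, cell aggregates grown from such stem cells to resemble the blastocyst. Libraries were made with Smart-seq2, which amplifies full-length cDNA by PCR without molecular identifiers. The 19 libraries formed 7 groups. In 2D culture there were 2 untreated control libraries and 2 libraries of cells given 20 nM pladienolide B (PlaB), a compound that binds the SF3B complex of the spliceosome, for 6 h, all taken 54 h after seeding. In 3D microwells there were 3 libraries from each of days 1 to 5 of blastoid culture, which the labels also list as PlaB-treated. The control libraries held 4118725 and 3909958 counts, and the PlaB libraries 2515381 and 2765115. Blastoid libraries held 6816649, 3684787 and 6750636 counts on day 1, 5889140, 7291420 and 6879886 on day 2, 6859777, 6841637 and 4231669 on day 3, 7607021, 6844130 and 6563862 on day 4, and 5330755, 4093751 and 5523515 on day 5. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Every replicate pair differed by more than counting error, with a chi-square per degree of freedom between 4.24 and 90.5.

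Other properties of the libraries moved with the groups. Mitochondrially encoded genes took 5.96% ± 0.31 of the counts in control cells (mean ± SD, n = 2) and 9.26% ± 0.169 after PlaB (n = 2). In blastoids the share was 3.45% ± 1.28 on day 1, 4.80% ± 0.99 on day 2, 7.90% ± 4.86 on day 3, 5.03% ± 1.47 on day 4 and 4.03% ± 0.606 on day 5 (n = 3 each). The high spread on day 3 came from replicate 3, in which 13.5% of the counts were mitochondrial (95% Wilson interval 13.46 to 13.52), against 5.50% and 4.71% in the other day 3 libraries. Levels of GC-rich genes relative to GC-poor genes also differed between groups. For each library, the median deviation of GC-poor genes from each gene's mean log2 level over all libraries was subtracted from that of GC-rich genes. The group mean of this difference was -1.07 in control cells, 0.19 after PlaB, and 1.04, 0.15, -0.76, 0.53 and -0.29 on blastoid days 1 to 5. Markers of fibroblasts, which the feeder cells express, had a median log2(CPM + 1) of 4.62 and 5.15 in the control libraries and of 6.145 and 6.163 in the PlaB libraries. In blastoids that median lay between 3.09 and 3.94 on day 1, between 1.01 and 2.03 on day 4 and between 1.26 and 1.40 on day 5.

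**Figure D1:**
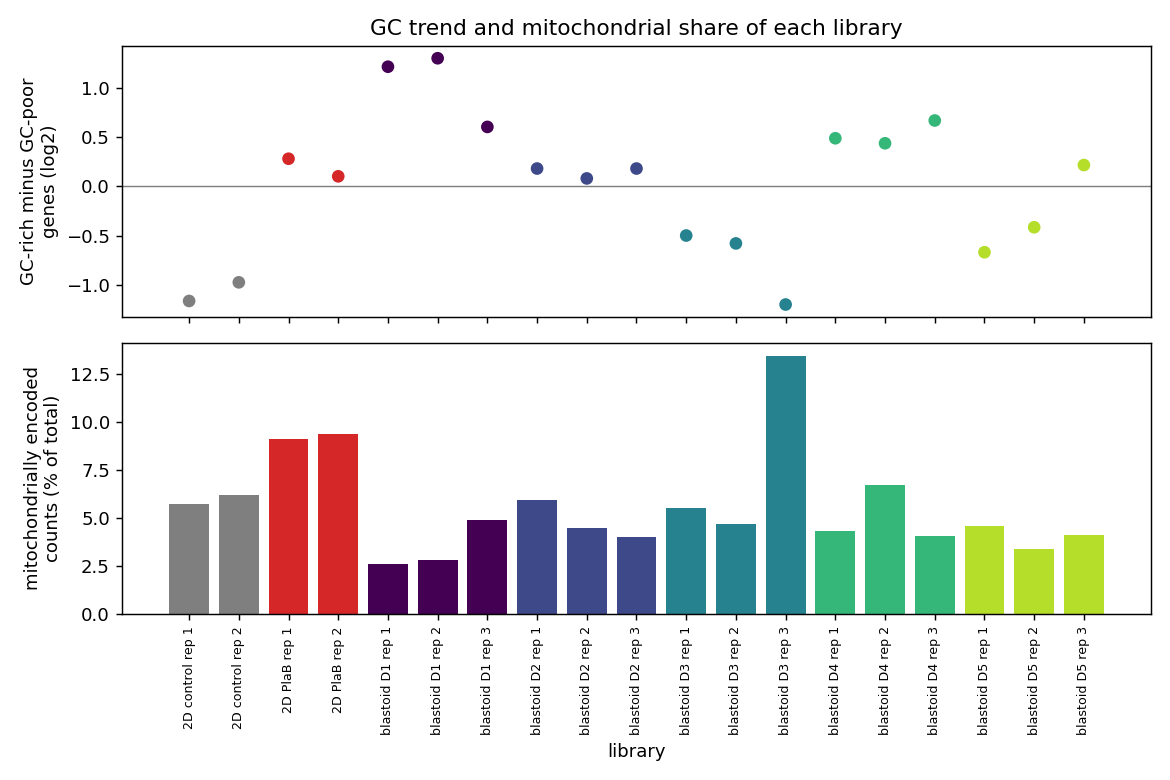
Upper panel, GC difference of each of the 19 libraries (points). It is the median deviation of GC-rich genes from each gene's mean log2 level over all libraries, minus that of GC-poor genes. Lower panel, share of counts from mitochondrially encoded genes in percent of the library total (bars). The group means of the GC difference run from -1.07 in control cells to 1.04 on blastoid day 1, and day 3 replicate 3 has the highest mitochondrial share, 13.5%.

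The 2D comparison asked what a short treatment with the splicing inhibitor did to the transcriptome of the stem cell cultures. It also asked whether the treatment switched on genes of the cleavage-stage embryo. Fibroblast markers were higher in the PlaB libraries, at a median log2(CPM + 1) of 6.145 and 6.163 against 4.62 and 5.15 in control. The changes after PlaB therefore cannot be assigned to the stem cells or to the feeder cells. Mdm2, which encodes the ubiquitin ligase that restrains p53 (chromosome 10, 117688875 to 117710758), rose from 215 ± 20.8 to 1828 ± 40.9 CPM (mean ± SD, n = 2 per group), a log2 fold change of 3.09 ± 0.13 (SE; adjusted p = 9.73e-20, edgeR quasi-likelihood test). Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases (chromosome 17, 29090976 to 29100727), rose by 1.79 ± 0.20 on the log2 scale, from 68.4 ± 28.6 to 236 ± 11 CPM (adjusted p = 7.66e-07). The antiproliferative gene Btg2 (2.23 ± 0.17), the stress-induced gene Ddit4l (2.31 ± 0.21) and the kinase gene Plk2 (1.81 ± 0.15) rose as well. Ccng1, another p53 target, stood at 603 ± 18.5 CPM against 611 ± 3.06 (log2 fold change -0.02, adjusted p = 0.915), but had a log2 fold change of 0.48 after correction for GC content (adjusted p = 0.0013). Of 27 measured p53 targets, 16 rose, 4 fell and 7 did not pass, and adjusted over the list alone 16 rose and 5 fell. The list as a whole was higher than other genes (median log2 fold change 0.67, camera adjusted p = 0.0137; adjusted p = 0.68 with an estimated correlation).

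Genes of the 2C stage, when the mouse embryo starts its own transcription, moved apart. Of 18 measured members 9 rose, 4 fell and 5 did not pass, with the same counts when adjusted over the list alone, and the list test missed the threshold (median 0.93, adjusted p = 0.171). It passed after GC correction (median 1.27, adjusted p = 0.0306; 12 rose and 3 fell), but had an adjusted p = 0.68 with an estimated correlation on uncorrected values. The PRAME-family gene Gm12794 rose by 2.52 ± 0.30 (adjusted p = 9.41e-09), Gm21761 by 3.54 ± 0.70 (adjusted p = 6.25e-05) and Tcstv1 by 2.06 ± 0.41, from 4.46 ± 0.831 to 18.8 ± 8.77 CPM (adjusted p = 6.2e-05). In contrast, Gm2016 fell by 2.62 ± 0.37 (adjusted p = 2.5e-07). Usp17le had a log2 fold change of 2.41 ± 0.71 (adjusted p = 0.00492), a call that ended with DESeq2 (adjusted p = 0.0979), without control replicate 1 (0.0678), without control replicate 2 (0.115) and without PlaB replicate 2 (0.0888). Where a 2D library is left out, its group holds 1 library, which is assumed to vary like those of the other groups in the fit. Zscan4c, which marks 2C-like cells in stem cell cultures, was at 35.6 ± 6.96 CPM after PlaB against 29.0 ± 6.32 (log2 fold change 0.29, adjusted p = 0.312; 0.72 and 0.0111 after GC correction). Zscan4d had a log2 fold change of -0.25 (adjusted p = 0.437). Duxf3, the gene of the 2C transcription factor Dux, had 0 counts in all 4 libraries of 2D culture. Zfp352, with 16 counts in the control libraries and 10 after PlaB, and Tcstv3, with 4 and 2, were too low to test. Dux, Zscan4, Usp17l, Tcstv and PRAME-family genes have near-identical copies between which reads cannot be assigned with certainty. Single members of these families are therefore uncertain, and the 0 counts of Duxf3 do not show that it was silent.

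Pluripotency genes were divided. Sox2 (log2 fold change -0.09, adjusted p = 0.67), Nanog (0.17, adjusted p = 0.324) and Klf4 (0.28, adjusted p = 0.133) did not pass, whereas after GC correction Nanog was higher (0.41, adjusted p = 0.0143) and Klf4 lower (-0.48, adjusted p = 0.0126). The naive-state markers Zfp42 and Klf5 fell by 0.87 ± 0.14 and 1.70 ± 0.17, and the Nodal co-receptor gene Tdgf1 fell by 1.5 ± 0.13, whereas Gdf3 (1.73 ± 0.17) and Tcl1 (1.87 ± 0.21) rose. Pou5f1, the gene of Oct4 (chromosome 17, 35506018 to 35510772), had only 4 counts over both control libraries and 81 over both PlaB libraries. This gave 0.495 ± 0.0145 and 16.0 ± 7.47 CPM and a log2 fold change of 4.91 ± 0.63 (adjusted p = 4.04e-08). The control level is low for a marker of stem cells, and the counting of reads at this locus is uncertain. The rise of Pou5f1 is therefore uncertain too. Of 27 naive and general pluripotency genes 6 rose, 9 fell and 12 did not pass, the same when adjusted over the list alone (adjusted p = 0.706), and here the median of 0.00882 and mean of 0.0162 were positive while the test pointed down. Among 12 formative and primed pluripotency genes 1 rose and 3 fell (adjusted p = 0.437), including Etv5 (-2.47 ± 0.26) and Grhl2 (-2.01 ± 0.53).

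The lists of G2 and M phase, immediate early and fibroblast genes passed the list test, though none with an estimated correlation. Of 26 genes of G2 and M phase, 3 rose and 15 fell (median -0.49, camera adjusted p = 0.0199; adjusted p = 0.68 with an estimated correlation). Among those that fell were the kinetochore motor gene Cenpe (-2.04 ± 0.16), Cenpf (-1.59 ± 0.14), the cytokinesis gene Anln (-1.66 ± 0.16) and the topoisomerase gene Top2a (-1.21 ± 0.12). Without PlaB replicate 2 this list missed the threshold (median -0.41, adjusted p = 0.0546). Of 17 immediate early genes 11 rose and 0 fell (median 1.12, adjusted p = 0.00992; adjusted p = 0.68 with an estimated correlation), including Ier3 (2.15 ± 0.20), Klf10 (1.32 ± 0.15) and the phosphatase gene Dusp6 (1.12 ± 0.15). After GC correction 8 rose and 2 fell, and the list no longer passed (median 0.58, adjusted p = 0.197). Of 22 fibroblast markers 17 rose and 1 fell (median 0.92, adjusted p = 0.00328; adjusted p = 0.68 with an estimated correlation), led by Bgn (2.00 ± 0.14), Col1a1 (1.75 ± 0.21) and Mmp2 (1.72 ± 0.24). GC correction left 12 higher and 2 lower, with a median of 0.55 (adjusted p = 0.128). Counts adjusted over each of these lists alone were the same.

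Splicing genes were divided too. Sf3b1, whose product is the direct partner of PlaB, had a log2 fold change of 0.29 ± 0.12 at the edge of the threshold (adjusted p = 0.0496). The call ended with DESeq2 (0.133), with RLE factors (0.0554), with total-count scaling (0.0935), with no filter (0.213), without control replicate 1 (0.184), without control replicate 2 (0.22) and without PlaB replicate 2 (0.289). Of 41 splicing factors 24 rose and 9 fell, and 25 rose and 10 fell adjusted over the list alone (median 0.53, adjusted p = 0.0594). This list passed after GC correction (adjusted p = 0.0306) and with no low-count filter (0.0241), but not with an estimated correlation in the fit of the 2D libraries (0.68). Its median was 0.555 without PlaB replicate 2. Sf3b5, another SF3B subunit with no introns, rose by 3.30 ± 0.17, Snrpb by 2.7 ± 0.18 and Sf3b3 by 1.57 ± 0.14, while the splicing regulator gene Srsf10 fell by 1.66 ± 0.14. The number of introns ordered the genes at both ends. The 1350 genes without introns had a median log2 fold change of 0.36, the 1603 with 1 to 2 introns 0.05, the 4430 with 3 to 9 introns 0.06 and the 3754 with 10 or more introns -0.20. Intronless genes were higher than other genes of known intron number by camera (p = 0.00129), but not with an estimated correlation (p = 0.0862).

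**Figure D2:**
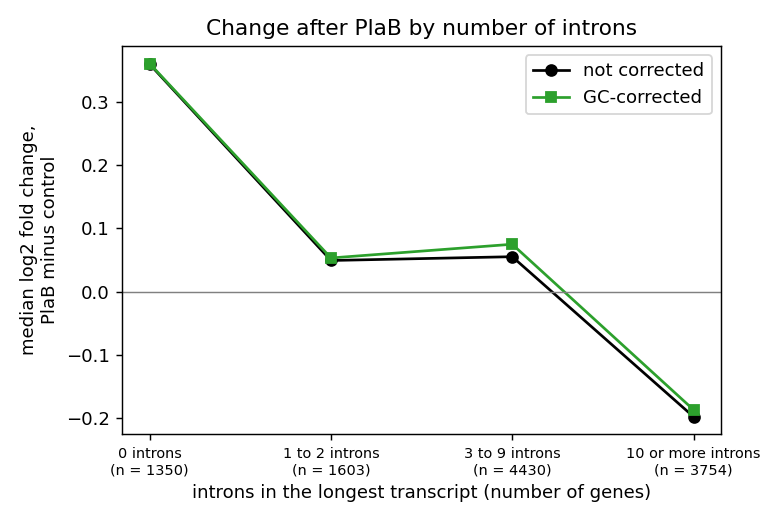
Median log2 fold change between PlaB and control against the number of introns in the longest transcript of each gene, for genes grouped into 4 classes (the number of genes in each class is given on the axis); circles are uncorrected and squares GC-corrected values. Genes without introns lie at 0.36 in both, and genes with 10 or more introns at -0.20 and -0.19.

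The other lists did not pass as groups. Apoptosis regulators had 2 higher and 4 lower of 13 (adjusted p = 0.257), and the inhibitor-of-apoptosis genes Xiap (-2.02 ± 0.18) and Birc2 (-2.58 ± 0.24) and the BCL2-family gene Mcl1 (-0.94 ± 0.14) were among those that fell. Ribosomal protein genes had 30 higher and 19 lower of 85 (adjusted p = 0.218) and S phase genes 8 and 6 of 25 (adjusted p = 0.593), with Slbp lower (-1.72 ± 0.15) and Gins2 higher (2.71 ± 0.26). Stress and unfolded protein response genes had 8 and 5 of 17 (adjusted p = 0.317), with the serine synthesis gene Phgdh at 2.74 ± 0.26 and Atf4 at 1.38 ± 0.15. Glycolysis and hypoxia genes had 16 higher and 7 lower of 27 (adjusted p = 0.0657; 0.0285 without control replicate 2, 0.0207 with no filter and 0.68 with an estimated correlation), with Gapdh at 2.72 ± 0.15 and Eno1 at 2.30 ± 0.15. Cholesterol synthesis genes had 11 higher and 1 lower of 21 (adjusted p = 0.0657; 0.0138 with no filter and 0.68 with an estimated correlation), Fdft1 rising by 1.68 ± 0.17 and Sqle falling by 1.24 ± 0.25. Primitive endoderm markers had 8 higher and 1 lower of 19 (adjusted p = 0.0914), led by Apoe (3.96 ± 0.18) and Sparc (1.61 ± 0.13). Trophectoderm markers had 6 higher and 4 lower of 15 (adjusted p = 0.964), with a median of -0.245 under a test that pointed up. In that list Lgals3 (1.96 ± 0.17) and the keratin gene Krt8 (2.06 ± 0.24) rose, and Krt18 (1.37 ± 0.22, adjusted p = 1e-05) did not pass after GC correction (0.41, adjusted p = 0.0916). Epithelial junction genes had 6 higher and 6 lower of 21 (adjusted p = 0.706), YAP targets 5 and 3 of 11 (adjusted p = 0.32), with Cyr61 at 2.62 ± 0.14, and Nodal targets 1 and 2 of 7 (adjusted p = 0.343). Adjusted over the list alone, 9 stress genes and 12 cholesterol genes were higher, and the other counts of this paragraph were the same. Mesendoderm and Wnt lists had fewer than 3 tested genes.

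By size, the genes that rose most by the fixed rule, with no overlap between the libraries of both groups, were Olfr458, Rpl36al, Mpv17l2, Olfr457, Pou5f1, Tppp3, Cyba and Tspan4, and those that fell most were Mterf1b, Zfp87, Slco4c1, Gen1, Zfp953, Prdm14, Srek1ip1 and Ptgs2os2. Rpl36al, an intronless ribosomal protein gene, rose by 5.31 ± 0.57 (26.2 ± 9.31 against 0.631 ± 0.893 CPM), Cyba, a subunit of the phagocyte NADPH oxidase, by 4.54 ± 0.38. Gen1, a nuclease that resolves Holliday junctions, fell by 4.53 ± 0.43 (1.33 ± 0.728 against 32.2 ± 3.78 CPM). Several had so few counts in the lower group that only a ratio with its 95% counting interval can be given. It was 53.4 (14.2 to 450) for Olfr458, 39.8 (13.1 to 197) for Mpv17l2 and 33.0 (10.8 to 164) for Olfr457, all higher. For genes that fell it was 17.4 (5.75 to 86.1) for the pluripotency gene Prdm14, 26.9 (9.01 to 132) for Mterf1b, 27.0 (7.26 to 227) for Zfp87 and for Slco4c1, and 18.5 (6.11 to 91.2) for Zfp953. These intervals, and the floors used below, cover counting error only, since PCR reads are not independent molecules.

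Across the transcriptome 2897 of 11183 tested genes rose and 2887 fell, and 2005 and 1730 of these changed at least 2-fold. DESeq2 called 1808 higher and 1889 lower. The change followed GC content: its Spearman correlation with the log2 fold change was 0.43 across genes, which are not independent replicates, and the median log2 fold change ran from -0.54 in genes under 42% GC to 1.04 in genes over 54%. With each library's GC trend removed, 2673 genes were higher and 2498 lower, 70.3% of the original calls held in the same direction, and 22 were called in the opposite direction.

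**Figure D3:**
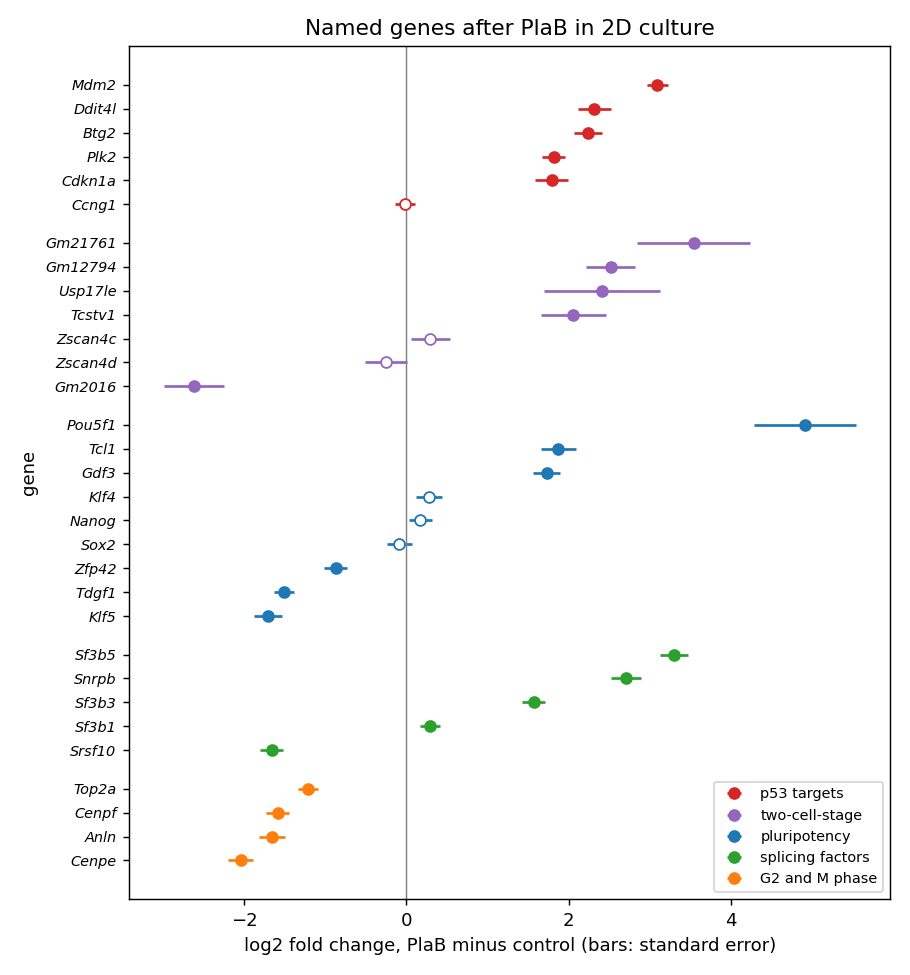
Log2 fold change between PlaB and control (horizontal axis) for named genes of 5 lists (vertical axis); points are fitted values, bars are standard errors, and open points mark genes with an adjusted p above 0.05. Mdm2 lies at 3.09 and Cenpe at -2.04, with Zscan4c, Zscan4d, Nanog, Sox2, Klf4 and Ccng1 open near 0.

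The blastoid series asked how expression changed from aggregates of day 1 to blastoids of day 5. Gata3, a transcription factor gene of the trophectoderm (chromosome 2, 9857078 to 9890034), rose from 2.75 ± 0.543 to 32 ± 14.5 CPM (mean ± SD, n = 3 per day), a log2 fold change of 3.55 ± 0.35 (adjusted p = 1.73e-07). The simple-epithelium keratin genes Krt8 (chromosome 15, 101996698 to 102004482) and Krt18 (chromosome 15, 102028180 to 102032027) rose by 1.98 ± 0.30 and 1.87 ± 0.29, reaching 350 ± 115 and 909 ± 366 CPM. Nanog (chromosome 6, 122707489 to 122714633) fell by 2.97 ± 0.24, from 311 ± 67.3 to 39.8 ± 8.22 CPM (adjusted p = 2.31e-08), and Pou5f1 fell by 4.32 ± 0.37, from 38.5 ± 10.8 to 1.88 ± 0.581 CPM. Pou5f1 had only 2 counts in each control library of stem cells, and the counting of reads at its locus is uncertain. Its changes, here and in the other comparisons, are therefore uncertain too. Sox2 fell by 1.04 ± 0.33 (adjusted p = 0.0123), a call that ended without day 5 replicate 3 (-0.86, adjusted p = 0.0592).

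Of 28 trophectoderm markers, 15 rose, 3 fell and 10 did not pass, and 16 rose adjusted over the list alone. The list was higher on day 5 (median 1.23, adjusted p = 0.000979; adjusted p = 0.531 with an estimated correlation), with the placental gene Plac1 at 3.97 ± 0.35, Gata2 at 2.87 ± 0.26 and the receptor gene Fgfr2 at 3.23 ± 0.33. Eomes had a log2 fold change of -0.67 (adjusted p = 0.164; 0.0462 with total-count scaling), and Cdx2, with 16, 0, 5, 21 and 1 counts on days 1 to 5, was too low to test. Of 23 epithelial junction and fluid transport genes 14 rose and 4 fell, 15 rising adjusted over the list alone (median 1.03, adjusted p = 0.00147; adjusted p = 0.531 with an estimated correlation). Among them were the desmosome genes Pkp2 (3.49 ± 0.27) and Dsp (2.55 ± 0.30) and the tight junction genes Ocln (3.90 ± 0.33) and Cgn (2.93 ± 0.26). Glycolysis and hypoxia genes had 16 higher and 2 lower of 28 (median 1.5, adjusted p = 1.9e-05; adjusted p = 0.531 with an estimated correlation), led by Bnip3 (4.18 ± 0.29), Ndrg1 (3.33 ± 0.30) and Egln1, which encodes an oxygen-sensing hydroxylase (3.20 ± 0.29). Of 87 ribosomal protein genes 53 rose and 7 fell and 54 rose over the list alone (median 1.05, adjusted p = 1.05e-05; adjusted p = 0.764 with an estimated correlation), with Rps28 at 2.61 ± 0.34, and Rps4l, a retrocopy-like gene without introns, at -2.65 ± 0.32. YAP targets had 7 higher and 2 lower of 12, 8 higher over the list alone (median 0.93, adjusted p = 0.0466; adjusted p = 0.531 with an estimated correlation), with Amotl2 at 3.14 ± 0.31, Crim1 at 3.06 ± 0.50 and Axl at -3.15 ± 0.56. The YAP call ended without day 1 replicate 3 (adjusted p = 0.0946), day 5 replicate 1 (0.0739) or day 5 replicate 3 (0.0659).

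Of 27 naive and general pluripotency genes 3 rose and 14 fell (median -0.76, adjusted p = 0.0264; adjusted p = 0.64 with an estimated correlation), including Utf1 (-5.42 ± 0.39) and Gdf3 (-3.63 ± 0.35). This list did not pass after GC correction (median -0.476, adjusted p = 0.0875) or without day 5 replicate 1 (adjusted p = 0.0826). Not all of its members fell. With CPM scaled over all libraries, Klf4 stood at 49, 40.4 and 53.9 on day 1 and at 321, 383 and 212 on day 5. Zfp42 stood at 370, 326 and 365 on day 1 and at 281, 477 and 361 on day 5. Among the fixed lists, fibroblast markers of the feeder layer fell furthest, 0 of 22 rising and 18 falling, 19 adjusted over the list alone (median -2.80, adjusted p = 4.25e-05, or 0.531 with an estimated correlation). Bgn fell by 6.03 ± 0.55, and Col1a1 went from 136 counts over the day 1 libraries to 3 over those of day 5, a ratio of 31.2 (10.5 to 153).

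Markers of the primitive endoderm had 3 higher and 11 lower of 23, 12 lower over the list alone (adjusted p = 0.347), the laminin and collagen genes Lamb1 (2.05 ± 0.30) and Col4a2 (1.76 ± 0.27) rising and Pdgfra falling by 2.46 ± 0.52. Gata6 stood at 2.81 ± 0.263 CPM on day 5 and 2.80 ± 1.14 on day 1 (adjusted p = 0.928). Gata4, with 13, 7, 8, 17 and 6 counts on days 1 to 5, and Sox17, with 17, 3, 9, 22 and 9, were too low to test. Among 27 genes of the 2C stage 1 rose and 1 fell, and none passed over the list alone (adjusted p = 0.352), with a median of -0.332 under a test that pointed up. Leaving out day 1 replicate 3 brought that list past the threshold (median 0.76, adjusted p = 0.0384), while all libraries gave an adjusted p = 0.833 with an estimated correlation. The member that rose, Gm2016 (1.58 ± 0.50), did not pass without day 5 replicate 2 (adjusted p = 0.0817) or after GC correction (1.08, 0.0507). The member that fell, Usp17le (-1.55 ± 0.64, adjusted p = 0.0492), did not pass without day 1 replicate 3 (0.648), day 5 replicate 1 (0.192) or day 5 replicate 2 (0.0923), with DESeq2 (0.0737) or after GC correction (-1.41, 0.0706). Zscan4d had a log2 fold change of -0.33 (adjusted p = 0.732) and Zfp352, with 18 counts on day 1 and 3 on day 5, a ratio of 4.13 (1.21 to 21.9; adjusted p = 0.208). Of the day 1 counts of Zfp352, 17 were in replicate 1, so its counting interval rests on that library.

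No other list passed. The p53 targets had 15 higher and 10 lower of 30 (adjusted p = 0.538; median 0.38, mean -0.0467), with Phlda3 at -4.64 ± 0.43 and Plk2 at 1.48 ± 0.22. Formative and primed pluripotency genes had 2 higher and 7 lower of 14 (adjusted p = 0.217). Splicing factors had 14 and 13 of 42 (adjusted p = 0.892; median 0.16, mean -0.16), with the kinase genes Clk1 (2.47 ± 0.25) and Clk4 (2.16 ± 0.22) higher and Sf3b4 (-4.38 ± 0.42) and Snrpa (-3.64 ± 0.24) lower. Stress and unfolded protein response genes had 7 and 7 of 19 (adjusted p = 0.638) and immediate early genes 8 and 5 of 18 (adjusted p = 0.505), the shared member Atf3 rising by 4.45 ± 0.33. Apoptosis regulators had 5 and 4 of 17 (adjusted p = 0.538), and S phase genes 6 and 10 of 25 (adjusted p = 0.101). G2 and M phase genes had 11 and 7 of 26 (adjusted p = 0.728; median 0.04, mean -0.0124), cholesterol synthesis genes 6 and 8 of 21 (adjusted p = 0.53; median 0.08, mean -0.29) and Nodal targets 1 and 2 of 5 (adjusted p = 0.853; median 0.08, mean -0.0488). Wnt targets had 3 and 2 of 10 (adjusted p = 0.638), with Axin2 at 1.46 ± 0.36 and Lgr5 at 3.53 ± 0.80. The mesendoderm list had 0 higher and 2 lower of 4 (adjusted p = 0.199), Bmp4 (-2.93 ± 0.34) and Cdx1 (-4.38 ± 0.49), and passed without day 1 replicate 2 (adjusted p = 0.0178; 0.531 with an estimated correlation and all libraries). Adjusted over the list alone, 14 splicing factors, 6 immediate early genes and 12 S phase genes were lower, and the other counts of this paragraph were the same. With no low-count filter the formative (adjusted p = 0.0216), primitive endoderm (0.00474), mesendoderm (0.00598), S phase (0.000594) and cholesterol lists (0.0495) also passed, all lower. With the filter and an estimated correlation their adjusted p values were 0.64, 0.833, 0.531, 0.804 and 0.833.

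**Figure D4:**
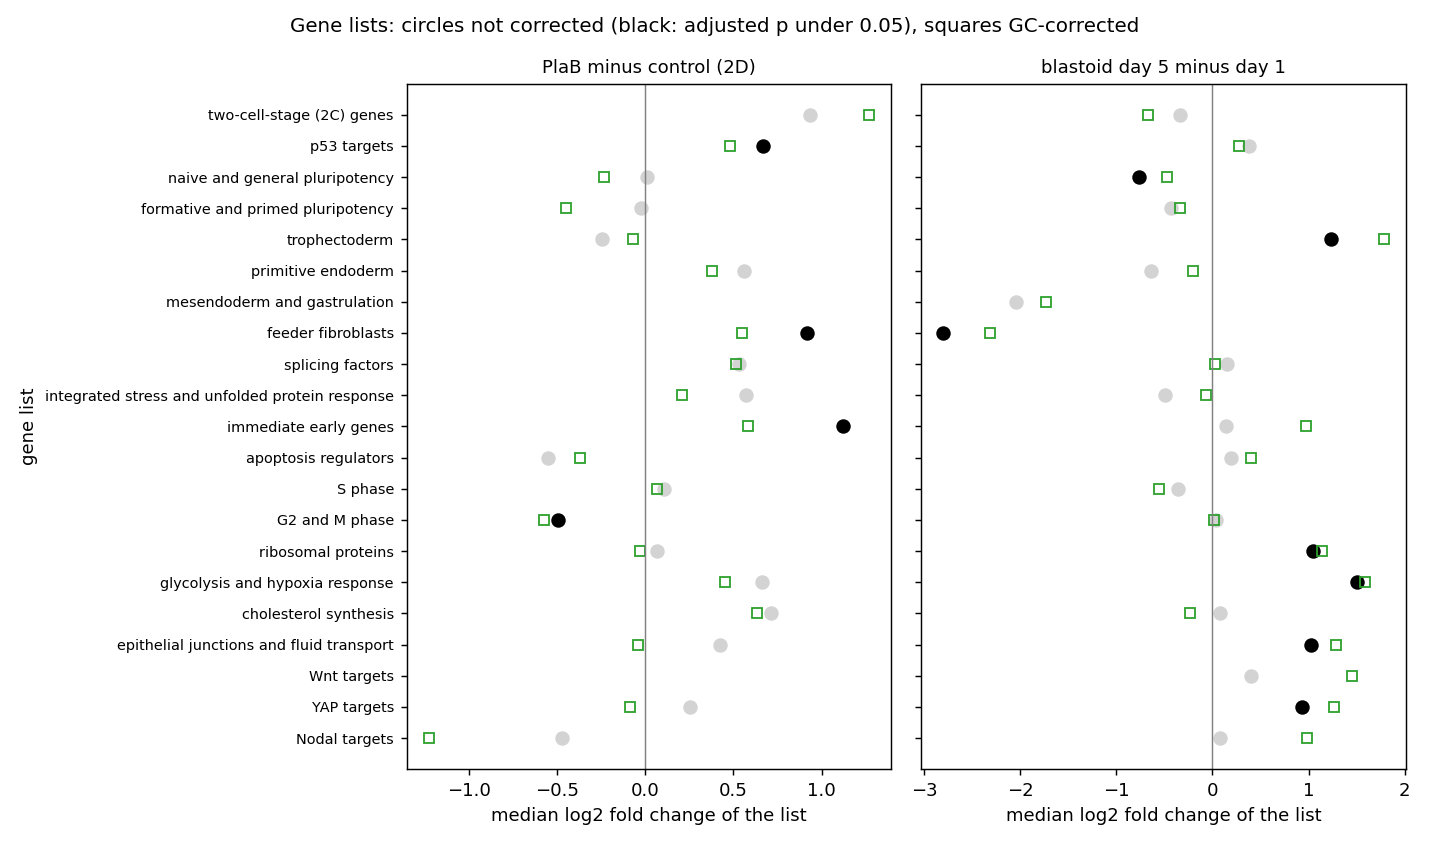
Median log2 fold change of each gene list (horizontal axis) for PlaB minus control (left) and blastoid day 5 minus day 1 (right); circles are uncorrected medians, black where the camera adjusted p is under 0.05, and squares are GC-corrected medians. Fibroblast markers lie at 0.92 after PlaB and at -2.80 on day 5, and trophectoderm markers at 1.23 on day 5.

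The largest changes by the fixed rule included 4 members of the Serpinb9 cluster of protease inhibitor genes on chromosome 13. Serpinb9f, with 372 counts over the day 5 libraries and 0 over those of day 1, was at least 180-fold higher, taking the day 1 group at a floor of 3 counts over the group. Ratios on day 5 were 504 (89.9 to 20000) for Serpinb9g, 150 (50.7 to 730) for Serpinb9d and 105 (28.4 to 872) for the lipoxygenase gene Alox12b. Serpinb9e rose by 7.52 ± 0.79, Fam90a1b by 7.80 ± 0.70, Mal by 5.70 ± 0.62 and Afap1l2 by 5.03 ± 0.53. Reads of the Serpinb9 copies may be split between near-identical genes, so their single values are uncertain. In the other direction the interleukin receptor gene Il1rl1 was at least 52.5-fold lower, and the ratios were 409 (113 to 3380) for Lce1g, 213 (37.9 to 8430) for Ch25h and 118 (21 to 4700) for Spink1. Log2 fold changes were -7.24 ± 1.43 for Serpinb2, -6.95 ± 0.82 for the matrix gene Tnc, -6.29 ± 0.65 for Aebp1 and -6.17 ± 1.07 for the metalloproteinase gene Mmp3. Fibroblast markers fell too, from medians of log2(CPM + 1) between 3.09 and 3.94 on day 1 to between 1.26 and 1.40 on day 5. The falls named here therefore cannot be assigned to the blastoid cells or to feeder cells. The Spink1 call (adjusted p = 0.0442) ended with no low-count filter (0.13), without day 1 replicate 2 (0.278) and without day 5 replicate 1 (0.121), 2 (0.101) or 3 (0.132).

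Across the transcriptome 3863 of 15121 tested genes rose and 3855 fell from day 1 to day 5, 2865 and 3196 of them at least 2-fold. Scaling by total counts alone gave 2623 higher and 5145 lower, since it moved the median log2 fold change of all genes to -0.352 from -0.0154, and fold changes here are relative to the TMM scale. GC correction kept 79.7% of the calls.

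Over all 5 days, 10286 of 15121 genes differed between any days (9901 after GC correction). Of these, 2885 had their highest mean on day 1, 1019 on day 2, 2424 on day 3, 675 on day 4 and 3283 on day 5. Krt8 fell from 89.2 ± 28.9 CPM on day 1 to 30.1 ± 11.3 on day 2 and 10.8 ± 2.26 on day 3, then rose to 240 ± 15 on day 4 and stood at 350 ± 115 on day 5. Krt18 took the same course, with 249, 90.3, 25.4, 578 and 909 CPM. Sox2 was highest on day 3, with 47.4, 65.2, 184, 61.7 and 23.2 CPM, whereas Nanog had 311, 230, 155, 101 and 39.8 CPM. The days share libraries between neighbouring comparisons, and no overlap between the comparisons is given.

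**Figure D5:**
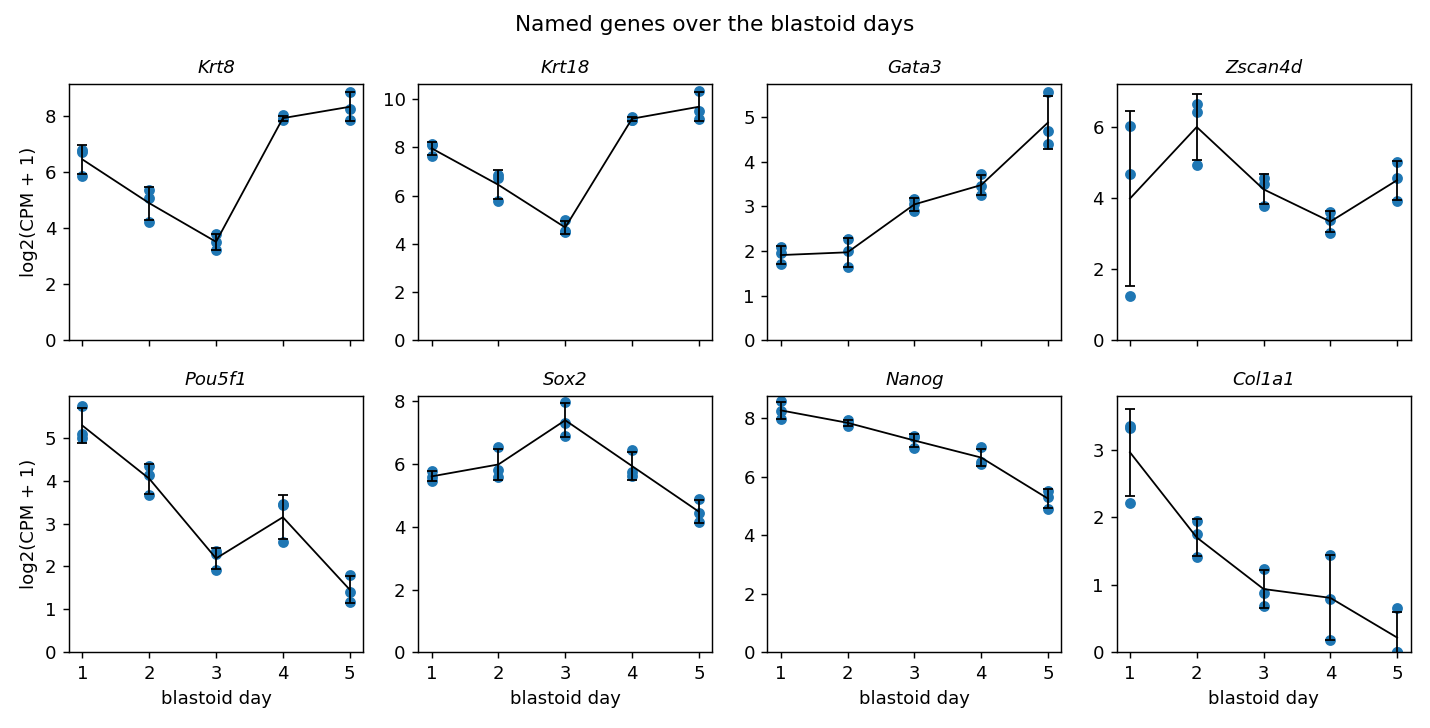
Levels of 8 named genes as log2(CPM + 1) (vertical axes) on blastoid days 1 to 5 (horizontal axes); points are single libraries (3 per day), lines join the means and bars are SD. Krt8 and Krt18 are lowest on day 3 and highest on day 5, and Nanog is highest on day 1 and lowest on day 5.

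From day 1 to day 2, Krt8 fell by 1.56 ± 0.30 (adjusted p = 0.0029), Krt18 by 1.46 ± 0.29 (adjusted p = 0.00383) and Pou5f1 by 1.28 ± 0.29 (adjusted p = 0.00861). The Pou5f1 call ended after GC correction (-0.64, adjusted p = 0.188), without day 1 replicate 1 (0.0872) and without day 2 replicate 1 (0.0665). The chemokine gene Ccl12 had a ratio of 66.3 (22.4 to 324), and Ccl8 (3.19 ± 0.57) and the class I gene H2-T23 (3.02 ± 0.60) rose, while Lypla2 (-4.58 ± 0.45), Ier5l (-4.48 ± 0.65) and Phlda3 (-4.38 ± 0.40) fell. Trophectoderm markers fell as a group, 0 higher and 13 lower of 28, 19 over the list alone (median -1.43, adjusted p = 1.7e-11; adjusted p = 0.0769 with an estimated correlation). So did p53 targets (0 and 6 of 30, adjusted p = 0.0191), immediate early genes (0 and 6 of 18, adjusted p = 0.00156) and epithelial genes (0 and 5 of 23, adjusted p = 0.00347), each with an adjusted p = 0.468 with an estimated correlation. Ribosomal protein genes had 8 higher and 0 lower of 87, 30 over the list alone (adjusted p = 2.2e-13), and the 2C list was higher as a group (median 0.83, adjusted p = 2.32e-07) with 0 of 27 members past the threshold. With an estimated correlation the ribosomal and 2C calls were lost too, both with an adjusted p = 0.468. Adjusted over the list alone, 7 p53 targets, 9 immediate early genes and 11 epithelial genes were lower, and 1 p53 target and 2 epithelial genes higher. Zscan4d had 29.5 ± 31.6 CPM on day 1 and 71.3 ± 37.5 on day 2 (adjusted p = 0.337; 0.0397 without day 1 replicate 3). In total 255 genes rose and 797 fell. Scaling by total counts gave 156 and 1373, with a median log2 fold change of all genes of -0.168, GC correction 210 and 402, and a fit of only these 6 libraries 731 and 1305. The total of 1052 fell to 426 without day 1 replicate 1, 440 without day 1 replicate 2, 538 without day 2 replicate 1, 582 without day 2 replicate 2 and 459 without day 2 replicate 3.

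From day 2 to day 3, Sox2 rose by 1.49 ± 0.32 (adjusted p = 0.00279) and Gata3 by 1.33 ± 0.35 (adjusted p = 0.00954; 0.0603 without day 2 replicate 2). In turn, Krt8 (-1.48 ± 0.32), Krt18 (-1.83 ± 0.30) and Pou5f1 (-2.09 ± 0.33) fell. The largest rises by the fixed rule were those of the heparan sulfate sulfotransferase gene Hs6st2 (3.5 ± 0.51), Serinc5 (2.51 ± 0.40) and Ammecr1 (2.46 ± 0.35). The largest falls were those of Lce1g (-3.73 ± 0.51), Cyba (-3.26 ± 0.45) and Efemp2 (-3.08 ± 0.42). Formative and primed pluripotency genes rose as a group, 5 higher and 0 lower of 14 (median 0.44, adjusted p = 0.0307; adjusted p = 0.59 with an estimated correlation). The 2C list fell (median -1.41, adjusted p = 0.0307; adjusted p = 0.983 with an estimated correlation), with 2 of 27 members past the threshold and 1 over the list alone. Without day 3 replicate 1 (adjusted p = 0.0638 for both lists) or day 3 replicate 2 (0.102 for the formative and 0.103 for the 2C list) neither list passed. The 2C list also did not pass without day 2 replicate 2 (0.127) or without its multi-copy families (0.331). Without day 3 replicate 3, the library with the high mitochondrial share, 4 lists passed, and after GC correction 7, against 0 with an estimated correlation. In total 1821 genes rose and 2045 fell, while GC correction gave 1616 and 1580 and kept 63.6% of these calls. That sum of 3866 was 2479 in a fit of only these 6 libraries, 2257 without day 2 replicate 2, 1883 without day 2 replicate 3 and 2495 without day 3 replicate 3.

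The step from day 3 to day 4 brought the keratins up. Krt8 rose by 4.47 ± 0.34 (adjusted p = 4.22e-08) and Krt18 by 4.5 ± 0.33 (adjusted p = 4.17e-08). The claudin gene Cldn3 (5.81 ± 0.54), the hypoxia-induced peptide gene Adm (5.66 ± 0.59) and Krt19 (5.43 ± 0.45) rose most by the fixed rule. Il6 (-4.67 ± 0.62), Prl2c3 (-4.35 ± 0.75) and Gldn (-4.34 ± 0.60) fell most, and Sox2 fell by 1.57 ± 0.32. Nanog had a log2 fold change of -0.62 (adjusted p = 0.0411) and Pou5f1 of 1.13 (adjusted p = 0.0162), but both calls ended after GC correction (-0.45 and 0.25, adjusted p = 0.152 and 0.625). The Nanog call also ended with total-count scaling (0.0981), with no filter (0.183), without day 3 replicate 1 (0.0777) or 2 (0.117) and without day 4 replicate 1 (0.126) or 2 (0.167), and that of Pou5f1 without day 4 replicate 2 (0.0709) or 3 (0.0741). Trophectoderm markers rose as a group, 22 of 28 higher and 0 lower, 23 and 2 over the list alone (median 2.74, adjusted p = 1.1e-10; adjusted p = 0.0925 with an estimated correlation). Glycolysis genes had 23 higher and 0 lower of 28 (adjusted p = 1.1e-10; adjusted p = 0.157 with an estimated correlation) and epithelial genes 11 and 0 of 23 (adjusted p = 0.000174; adjusted p = 0.365 with an estimated correlation). The p53 list was just past the threshold (9 higher and 1 lower of 30, 12 higher over the list alone, adjusted p = 0.0496; adjusted p = 0.632 with an estimated correlation), and missed it without day 3 replicate 1 (0.142) or 2 (0.058) and without day 4 replicate 1 (0.0794). Formative genes fell (1 higher and 7 lower of 14, adjusted p = 0.00673) and so did fibroblast markers (0 and 16 of 22, 17 lower over the list alone, median -2.07, adjusted p = 2.41e-09), both with an adjusted p = 0.236 with an estimated correlation. In total 2361 genes rose and 1863 fell, whereas total-count scaling gave 2879 and 1297. GC correction gave 1481 and 1388 and kept 51.6% of the calls, and the Spearman correlation of GC content with the log2 fold change was 0.552. The sum of 4224 was 2697 in a fit of only these 6 libraries and 2549 without day 4 replicate 3.

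From day 4 to day 5, Gata3 rose by 1.65 ± 0.31 (adjusted p = 0.000557), and Nanog (-1.34 ± 0.23), Sox2 (-1.42 ± 0.33) and Pou5f1 (-2.07 ± 0.38) fell. Krt8 did not pass (0.54, adjusted p = 0.167), but did after GC correction (1.08, adjusted p = 0.00354). The glycogen phosphorylase gene Pygm (4.29 ± 0.64), Ovgp1 (4.27 ± 0.56) and Hecw1 (4.00 ± 0.55) rose most. Among the falls, Cubn, which encodes an endocytic receptor, changed by -5.13 ± 1.26, and S100g (-5.81 ± 1.64, adjusted p = 0.0194) and Spink1, with a ratio of 368 (65.8 to 14600), varied widely on day 4, at 34.5 ± 44.5 and 26.5 ± 36.6 CPM. The S100g call ended with no filter (0.0629), without day 5 replicate 2 (0.064) or 3 (0.0708), and that of Spink1 (adjusted p = 0.0292) with no filter (0.0922), without day 4 replicate 1 (0.0738) or day 5 replicate 1 (0.107), 2 (0.0836) or 3 (0.0958). Epithelial genes had 12 higher and 0 lower of 23 (adjusted p = 0.00613), immediate early genes 9 and 2 of 18 (adjusted p = 0.0035) and trophectoderm markers 7 and 1 of 28 (adjusted p = 0.0315), each with an adjusted p = 0.564 with an estimated correlation. Adjusted over the list alone, 13 epithelial, 11 immediate early and 8 trophectoderm genes were higher and 2 trophectoderm genes lower. Naive pluripotency genes had 4 higher and 11 lower of 27, 12 lower over the list alone (adjusted p = 0.0197; adjusted p = 0.564 with an estimated correlation) and formative genes 0 and 6 of 14 (adjusted p = 0.00613; adjusted p = 0.564 with an estimated correlation). The 2C list was higher (5 and 0 of 27, 3 over the list alone, adjusted p = 0.0315; adjusted p = 0.875 with an estimated correlation), but not without its multi-copy families (0.141) or with no filter (0.137). After GC correction it missed the threshold with a similar median (0.819 against 0.977, adjusted p = 0.269). The trophectoderm call ended without day 4 replicate 2 (0.0687) or 3 (0.101) or day 5 replicate 3 (0.113) and with no filter (0.137), the 2C call without day 4 replicate 3 (0.109) or day 5 replicate 2 (0.141) or 3 (0.106), and the naive call without day 5 replicate 1 (0.0728). The feeder list had a median of -0.324 under a test that pointed up (adjusted p = 0.998). In total 2133 genes rose and 2188 fell, 1361 and 3004 with total-count scaling and 2233 and 1937 after GC correction, and the sum of 4321 was 2876 without day 5 replicate 1.

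The last comparison set blastoid day 1 against the PlaB-treated cells in 2D. Culture format, time and the table that held the counts changed together between these groups, so their effects were not separated. Levels of fibroblast markers differed as well. Their median log2(CPM + 1) was 6.145 and 6.163 in the PlaB libraries and 3.591, 3.943 and 3.093 on day 1. The changes below therefore cannot be assigned to the stem cells or to the feeder cells. Mdm2 was lower in day 1 blastoids, at 209 ± 9 CPM (n = 3) against 1940 ± 60.7 (n = 2), a log2 fold change of -3.22 ± 0.22 (adjusted p = 1.02e-10). The p53 targets Btg2 (-2.39 ± 0.22), Plk2 (-2.48 ± 0.23), Ddit4l (-2.05 ± 0.27) and Ccng1 (-0.92 ± 0.22) were also lower. Cdkn1a did not pass (-0.41, adjusted p = 0.377; -0.88 and 0.017 after GC correction). Of 30 p53 targets 4 were higher and 18 lower and 5 higher over the list alone (adjusted p = 0.00138; adjusted p = 0.217 with an estimated correlation). G2 and M phase genes were higher, 15 of 26 with 0 lower, 18 over the list alone (median 1.04, adjusted p = 1.87e-05; adjusted p = 0.217 with an estimated correlation), with Plk1 at 2.53 ± 0.36 and Cenpe at 1.76 ± 0.25. S phase genes had 13 higher and 1 lower of 26, 16 higher over the list alone (adjusted p = 0.00156; adjusted p = 0.328 with an estimated correlation).

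Trophectoderm markers were higher on day 1, 16 of 28 with 0 lower (median 1.55, or 1.53 with genes at 0 counts set to their bound, adjusted p = 4.53e-05; adjusted p = 0.217 with an estimated correlation). Id2 rose by 1.69 ± 0.23, and the ratio was 47.8 (8.48 to 1900) for Gata2 and 36.4 (12.4 to 177) for the epithelial factor gene Elf3. Epithelial genes had 9 higher and 0 lower of 22, 11 higher over the list alone (adjusted p = 0.024; adjusted p = 0.376 with an estimated correlation), a call that ended after GC correction (median 0.472 against 0.705, 0.0897), without PlaB replicate 2 (0.0802) and without day 1 replicate 2 (0.0541). Fibroblast markers fell, 0 higher and 19 lower of 22 (median -2.56, adjusted p = 3.07e-11; adjusted p = 0.217 with an estimated correlation). Examples are Col3a1 at -5.00 ± 0.34 and Postn at -4.47 ± 0.41. By the fixed rule, Acta2, the smooth muscle actin gene, was at -9.55 ± 0.78 (2.65 ± 2.17 against 1910 ± 565 CPM). YAP targets had 1 higher and 8 lower of 12 (median -3.29, adjusted p = 4.94e-06; adjusted p = 0.164 with an estimated correlation), led by Ctgf (-7.65 ± 0.44) and Ankrd1 (-7.62 ± 0.48). Immediate early genes (2 and 10 of 19, adjusted p = 0.000381), ribosomal protein genes (0 and 42 of 87, adjusted p = 6.14e-08), glycolysis and hypoxia genes (0 and 12 of 28, adjusted p = 0.000381) and Nodal targets (1 and 5 of 7, adjusted p = 0.00505) were lower as groups, at adjusted p values of 0.217, 0.376, 0.313 and 0.217 with an estimated correlation. Adjusted over the list alone, 11 immediate early and 43 ribosomal protein genes were lower. Ier5 (-4.63 ± 0.45), Vegfa (-4.59 ± 0.37) and Adm (-6.74 ± 0.44) were among their members, while Nodal itself was higher (1.78 ± 0.42). Primitive endoderm markers (3 and 9 of 27) and the 2C list (2 and 3 of 29) were lower at an adjusted p = 0.0366 (0.431 and 0.611 with an estimated correlation). Their medians were only -0.0827 and -0.0657. The primitive endoderm call ended without PlaB replicate 1 (0.068), day 1 replicate 1 (0.0801) or day 1 replicate 3 (0.145) and with no filter (0.204). The 2C call ended without its multi-copy families (0.163), with no filter (0.162), after GC correction (median -0.0559 against -0.0657, 0.264), without PlaB replicate 1 (0.169) and without day 1 replicate 2 (0.698). Naive and general pluripotency genes (11 and 3 of 27, adjusted p = 0.133), formative genes (4 and 3 of 15, adjusted p = 0.956; median -0.668, mean 0.0411), mesendoderm genes (2 and 0 of 6, adjusted p = 0.115), splicing factors (9 and 8 of 42, adjusted p = 0.543), and stress genes (6 and 5 of 19, adjusted p = 0.599) did not pass. The same held for apoptosis regulators (3 and 4 of 18, adjusted p = 0.511), cholesterol genes (7 and 0 of 22, adjusted p = 0.113) and Wnt targets (5 and 1 of 10, adjusted p = 0.115). Adjusted over the list alone, 1 gene of the 2C list, 4 apoptosis regulators and 6 cholesterol genes were higher, and 7 stress genes were higher and 6 lower. With no filter the naive (0.00128), mesendoderm (0.0283), splicing (0.0232), cholesterol (0.00144) and Wnt lists (0.00213) passed, as did the Wnt list without PlaB replicate 2 (0.0315) and the mesendoderm list without day 1 replicate 2 (0.0272). With the filter, all libraries and an estimated correlation their adjusted p was 0.569 for the naive, 0.779 for the splicing and 0.376 for each of the other lists.

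Of the single genes followed in both formats, Zfp42 was higher on day 1 (1.07 ± 0.26, adjusted p = 0.00213; 0.0505 without PlaB replicate 1) and Klf4 lower (-1.61 ± 0.31). Sox2 was lower (-1.10 ± 0.32, adjusted p = 0.00808; 0.058 with total-count scaling and 0.061 without PlaB replicate 2) and Pou5f1 higher (1.20 ± 0.36, adjusted p = 0.0101; 0.51 and 0.229 after GC correction, and adjusted p = 0.184 without PlaB replicate 2 and 0.0678 without day 1 replicate 1). Nanog (0.52, adjusted p = 0.0868; 0.00706 with total-count scaling), Sf3b1 (-0.21, adjusted p = 0.469), Zscan4c (-0.34, adjusted p = 0.761), Zscan4d (0.19, adjusted p = 0.884) and Usp17le (0.23, adjusted p = 0.807) did not pass. Tcstv3, with a ratio of 1 (0.2 to 9.68; adjusted p = 0.98), and Zfp352 (-1.26, adjusted p = 0.341; 0.0166 without day 1 replicate 1) did not pass either. Tcstv1 was lower (-2.33 ± 0.62, adjusted p = 0.00494; 0.112 without PlaB replicate 1). By the fixed rule the pseudophosphatase gene Sbf1 was at least 19-fold higher on day 1, with ratios of 139 (24.9 to 5520) for Lypla2, 95.9 (17.1 to 3800) for Dolpp1 and 86.1 (23.7 to 712) for Cdx1. The caveola gene Cavin2 was at least 313-fold lower, the nuclear receptor gene Nr4a3 at least 128-fold, and the ratio was 1080 (193 to 42900) for Sprr2k, again with floors of 3 counts over the group. Among the Nodal targets, the antagonist gene Lefty2 was at least 98.5-fold lower. In total 3569 of 16304 tested genes were higher and 2768 lower. Total-count scaling gave 4810 and 1954, moving the median log2 fold change of all genes to 0.43. The balance turned after GC correction (3058 and 3154) and in a fit of only the libraries compared (3012 and 3045). The counts were 2354 higher without PlaB replicate 1 and 2168 higher and 1643 lower without PlaB replicate 2.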

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

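Which corrections of GC content and length were tried was chosen after the result was seen. Sums of higher and lower genes were within 1.5 times their value under RLE, total-count scaling, limma-voom, thinning and the filter of at least 10 counts. Total-count scaling moved the separate counts further from day 1 to 2 (156 higher and 1373 lower, against 255 and 797) and from day 4 to 5 (1361 higher, against 2133). In simulated data 53% of 2-fold changes were recovered for PlaB and 20% for day 5 against day 1, where 4 of 6 libraries were deeper than any 2D library and the coefficient of variation larger (0.258 against 0.127). Thinning to the smallest total left 2727 genes higher and 2643 lower for PlaB and 3524 and 3449 for day 5 against day 1. No list passed with an estimated correlation, so 0 lists passed in each of the 7 comparisons. The cause of the changes below was not tested, except that a larger fold limit makes fewer calls by construction. With only 2 or 3 libraries per group, single libraries moved many counts.

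For PlaB against control, DESeq2 called 1808 genes higher and 1889 lower, and a log2 fold change of at least 1 left 1730 lower. Fry, which does not compare a list with other genes, called 8 lists and the fit with no filter 7, against 4. With GC correction, values turned for Ccng1 (0.48, adjusted p = 0.0013), Klf4 (-0.48, 0.0126), Fbln2 (-0.06, 0.769) and Smad7 (-0.33, 0.208). The Smad7 call (0.70, adjusted p = 0.00829) also ended with DESeq2 (0.133), without control replicate 1 (0.13) and without PlaB replicate 1 (0.111). The difference between intronless genes and those with 10 or more introns was 0.557, with p = 0.0862 by an estimated correlation, and ran from 0.461 without PlaB replicate 2 to 0.711 without control replicate 2. For day 5 against day 1, fry called 13 lists and the fit with no filter 12, against 7.

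From day 1 to day 2, 612 genes changed after GC correction, 603 after correction of GC and length and 2036 in a fit of only these libraries. Leaving out libraries gave 426 without day 1 replicate 1 to 1490 without day 1 replicate 3. The fit with no filter called 13 lists. The mesendoderm list turned, from a median of -0.00431 with an upward test to -0.934 with no filter (adjusted p = 0.0159) and -1.23 without day 1 replicate 2 (0.0419), and ran from -1.56 without day 2 replicate 1 to 0.292 without day 1 replicate 3. From day 2 to day 3 the count was 2479 in a fit of only these libraries and ran from 1883 without day 2 replicate 3 to 4669 without day 3 replicate 1. Fry called 5 lists, the fit with no filter 8, GC correction 7 and leaving out multi-copy families 1, and the number ran from 0 without day 3 replicate 1 to 4 without day 3 replicate 3. From day 3 to day 4 the count was 2697 in a fit of only these libraries and ran from 2549 without day 4 replicate 3 to 4591 without day 3 replicate 1, and fry and the fit with no filter each called 10 lists. From day 4 to day 5 it ran from 2876 without day 5 replicate 1 to 4367 without day 5 replicate 3.

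For day 1 against 2D PlaB, the count of higher genes ran from 2168 without PlaB replicate 2 to 3398 without day 1 replicate 3, and of lower genes from 1643 to 2568 for the same libraries. Replicate numbers were fitted as a block although they share only a number. The block gave 2301 higher and 1599 lower genes in this comparison, 2818 and 2836 for PlaB against control and 3662 and 3659 for day 5 against day 1. Correlations of residuals between libraries of the same number were -0.018 in 2D (2 pairs) and ran from -0.262 to 0.179 in blastoids, 4 of 30 pairs being over 0.1. The block ended 6 calls of named genes and 2 of lists and started 1 of a list.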

Other observations

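Families of genes were chosen after their values were seen, 15 in all, and tested in 7 comparisons with 104 tests adjusted together by camera. None passed with an estimated correlation. After PlaB, 18 of 26 interferon-induced genes rose and 2 fell (median 1.34, adjusted p = 0.00215; adjusted p = 0.367 with an estimated correlation), with the restriction factor gene Bst2 at 3.22 and Ifi202b at -0.76. Of 13 mitochondrially encoded genes 12 rose and 0 fell (median 0.805, adjusted p = 0.00208; adjusted p = 0.566 with an estimated correlation). In day 1 blastoids, against PlaB-treated 2D cells, 2 of 34 interferon-induced genes were higher and 21 lower (median -2.25, adjusted p = 5.51e-08; adjusted p = 0.157 with an estimated correlation), as were 0 and 11 of 22 chemokine genes (adjusted p = 7.26e-06; adjusted p = 0.141 with an estimated correlation). Fibroblast markers of the feeder cells moved the same way, by a median of 0.919 after PlaB and of -2.56 in day 1 blastoids.

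From day 1 to day 5, 6 of 7 Serpinb9 genes rose and 0 fell (adjusted p = 8.4e-05; adjusted p = 0.367 with an estimated correlation). Of 82 subunits of the respiratory chain 35 rose and 9 fell (median 0.591, adjusted p = 0.00588; adjusted p = 0.751 with an estimated correlation), while of 74 mitochondrial ribosomal protein genes 8 rose and 37 fell (median -0.728, adjusted p = 0.000152; adjusted p = 0.699 with an estimated correlation). Of 15 matrix metalloproteinase genes 0 rose and 11 fell (median -2.97, adjusted p = 0.00588; adjusted p = 0.547 with an estimated correlation). Fibroblast markers, a list that includes Mmp2, fell by a median of 2.80 in the same comparison.

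Pou5f1 had 4 counts over the control libraries, 81 over the PlaB libraries and 779, 317, 63, 176 and 26 over the libraries of blastoid days 1 to 5, low for a marker of embryonic stem cells. The antisense gene Gm19553, inside the same locus (chromosome 17, 35509077 to 35510551), had 0 counts in every library. Gm10800 (chromosome 2, 98666547 to 98667301), a predicted gene, took 2.465%, 2.547% and 1.927% of the counts on day 5 and between 0.0221% and 0.76% in the other libraries (day 5 against day 1, edgeR adjusted p = 6.58e-07).

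The tests of the 3 patterns below were chosen only after the result was seen. Intronless genes were higher after PlaB than genes with 10 or more introns by 0.557 (p = 0.0862 by camera with an estimated correlation). A library GC trend is unlikely to be the source, since the difference was 0.548 after GC correction. A transcript length trend is unlikely to account for all of it, since 0.408 was left after correction of GC and length. Impaired splicing of genes with introns is a hypothesis that gene counts did not test.

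The trophectoderm list was higher on day 5 than on day 1 by a median of 1.23. A library GC trend is unlikely to be the cause, as the median was 1.78 after GC correction (camera adjusted p = 1.73e-05), though uncorrected values gave an adjusted p = 0.531 with an estimated correlation. A lower share of feeder RNA on day 5 would raise all genes of the other cells alike. The trophectoderm list lay 2.26 above the naive and general pluripotency list after GC correction (permutation p = 4e-05, which treats genes as independent). A feeder share that acts on both lists alike would not part them. The fall of the naive list was known before this test was chosen. The gap therefore does not show how much a lower feeder share added to the trophectoderm rise.

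The feeder fibroblast list was higher after PlaB by a median of 0.919. A larger share of feeder RNA was left open. It would raise every marker alike, and Cochran's Q per degree of freedom over the markers was 19.6 after GC correction, but Q passed in 1000 of 1000 random lists of the same size (median 12.5), so it decided nothing. A library GC trend may have contributed, as the median fell to 0.548 after GC correction and the list no longer passed (adjusted p = 0.128), which leaves this open.

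Regrouping the 6 libraries of a blastoid comparison gives 10 splits, too few for a share under 0.05. From day 1 to day 5, 3863 genes higher and 3855 lower were found in the real split, against 0 in any other, so each value was reached in 1 of 10. The steps gave 1052, 3866, 4224 and 4321 changed genes in the real split and at most 0 in any other, again 1 of 10. Every other split puts libraries of both days in each group, which widens the spread of the fit. A count of 0 there does not measure how many calls arise by chance. Genes that differed between any days numbered 10286 with the real labels and at most 712 in the other draws of day labels, a value reached in 1 of 40. Random draws of the labels mix days within groups in the same way. The number of lists past the threshold was 7 from day 1 to day 5 (2 of 10 splits had as many, highest other 8), 6 from day 1 to 2 (6 of 10, highest other 9), 2 from day 2 to 3 (7 of 10, highest other 5), 6 from day 3 to 4 (3 of 10, highest other 9) and 6 from day 4 to 5 (1 of 10, highest other 5).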
